A study of Homo sapiens with 8 samples.

How the data were processed

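Gene expression was measured by RNA sequencing in 8 samples of the human line NOMO1, 4 with a control guide (sgLuc) and 4 with a guide against PSTK (sgPSTK). Per the labels, total RNA was extracted, polyadenylated RNA was selected and libraries were made with a kit whose reads do not keep the strand. The deposited table holds raw read counts per gene symbol, and the labels name STAR 2.7.3a, HTSeq 0.6.0 and the genome build hg19 without giving their roles or the annotation. The table lists 15115 genes in 16 columns, 2 per sample, tagged D4 and D7. The columns name the guide sgPSTK2 where the titles give sgPSTK, and were matched to the samples by guide and replicate number, with 0 columns left over. Genes with fewer than about 10 reads on average are not listed (lowest mean 9.94), and 0 mitochondrial genome genes are listed, by a filter that is not stated.

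The comparison planned before the data were examined used the counts summed over both columns of each sample. The same comparison within the D4 and within the D7 columns, and the difference between them with a term for each sample, were added after the columns were seen. Fits used edgeR 4.0.16 (quasi-likelihood, robust, TMM scaling) in R 4.3.3, after filterByExpr with a minimum count of 10 and a minimum total of 15, which removed 0 genes from the summed counts, 44 from D4 and 40 from D7. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Rose and fell refer to sgPSTK against sgLuc within the same columns, not to D7 against D4. Normalised CPM are counts divided by the scaled library total, given as mean and SD over 4 samples. Standard errors were taken from the log2 fold change and the F statistic.

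The 35 gene lists, with 843 genes of which 690 were found, were fixed before the data were examined. The 32 lists with at least 5 measured members were tested with camera from limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists, and again with an estimated correlation and with fry. In the D7 columns the estimate lay below the preset for the NRF2 (-0.0144), iron and heme (-0.0081) and lysosome (-0.0109) lists. A higher correlation between members thus does not explain the loss of those calls. For the other lists called in D7 it ranged from 0.0268 (selenoproteins) to 0.390 (erythroid). Named genes were taken from PSTK, the selenoproteins, the 12 largest rises and 12 largest falls among called genes with a mean of at least 2 CPM and no overlap between groups, and up to 4 members of each list with the smallest adjusted p. Genes outside that rule are members of the fixed lists or are stated to have been chosen later. Current symbols came from a newer annotation, in which 13130 of the 15115 symbols matched.

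Alternatives were DESeq2 size factors, library totals alone, the DESeq2 1.42.0 Wald test, limma voom with quality weights, no filter, the replicate number as a block, a test against 1.5-fold and leaving out each sample. Voom fits over the 16 columns, and over 14 columns without the sgLuc 1 D4 and sgLuc 2 D7 columns, were added after the data were seen. They held a term for the set and took the columns of a sample as correlated, with the sample as block. The replicate numbers were not treated as pairs. Samples of the same number correlated at 0.008 to 0.365 in the summed counts, where the same number was the best partner for 1 of 4, and at -0.142 to 0.451 within the sets. Within the sets the same number was the best partner for sgLuc 1 in D4 and for sgLuc 1, 3 and 4 in D7. None of the 24 pairs of columns within a group and set was a duplicate, and other pairs were not checked.

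Tested on simulated data with 4 samples per group, the summed fit recovered 71.7% of genes changed 1.5-fold and 88.7% of genes changed 2-fold, the D4 fit 30% and 61.1%, and the D7 fit 70.5% and 86.5%. Unchanged genes made up 11.4%, 5.83% and 7.45% of the calls. Simulated genes were drawn independently and no simulated library stood apart, unlike the sgLuc 1 D4 library, so the real recovery may differ. Totals of 21864400 to 33821200 counts per column set the precision, and intervals on counts cover counting error only, with 95% confidence and a floor of 3 counts for a group at 0.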

Results

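RNA sequencing of NOMO1 cells was used to ask how knockout of PSTK changes gene expression. The labels name the cells as NOMO1, which is known as an established human acute myeloid leukemia line of monocytic type, and their identity was not tested here. PSTK is the kinase that phosphorylates seryl-tRNA on the way to selenocysteine, the amino acid that defines selenoproteins. Cells carrying a CRISPR guide against PSTK (sgPSTK, 4 samples) were compared with cells carrying a control guide against luciferase (sgLuc, 4 samples). All sgPSTK columns name the same guide, so its effects on other genes cannot be told apart from loss of PSTK. Loss of the PSTK protein was not measured here. Each sample had 2 columns of gene counts, tagged D4 and D7. The labels do not say what the tags mean, and they are used here only as names of the sets. Totals ranged from 21864400 to 33821200 counts per column and from 45300600 to 58939400 per sample once the columns were summed. The labels do not say whether the samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

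In the summed counts the PSTK transcript stood at 6.21 ± 0.396 CPM in sgLuc and 4.87 ± 0.483 CPM in sgPSTK (SD, n = 4), a log2 fold change of -0.35 (SE 0.104, edgeR adjusted p = 0.112). Every sgLuc sample, at 5.65 to 6.52 CPM, lay above every sgPSTK sample, at 4.54 to 5.58 CPM. The difference passed with DESeq2 (adjusted p = 0.0328), with limma voom (adjusted p = 0.0163), with voom over the 16 columns (adjusted p = 0.0337) and in edgeR without sgLuc 4 (adjusted p = 0.0452). It did not pass with voom over 14 columns (adjusted p = 0.0826). The log2 fold change was -0.37 in the D4 columns (adjusted p = 1.0) and -0.35 in the D7 columns (adjusted p = 0.113). The groups did not overlap in the D4 columns (sgLuc 6.10 to 7.69 CPM, sgPSTK 4.52 to 5.78 CPM). They overlapped in the D7 columns (sgLuc 5.02 to 6.34 CPM, sgPSTK 3.94 to 5.29 CPM). These values rest on 93 to 268 PSTK reads per column. A guide acts on the gene and need not lower its transcript.

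**Figure D1:**
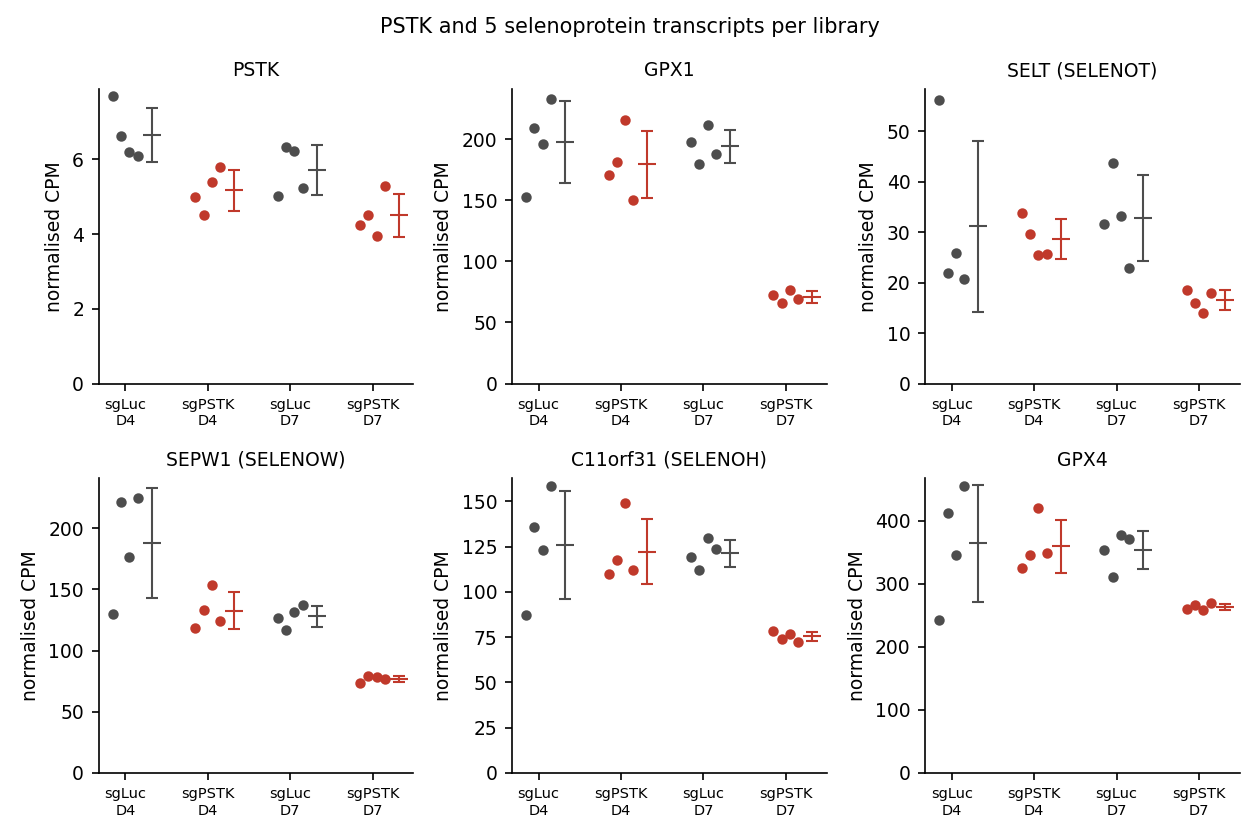
Normalised CPM of PSTK and of 5 selenoprotein transcripts in each library (points, 4 per group and set), with the mean and SD beside the points and every axis starting at 0. GPX1 lay between 65.9 and 76.6 CPM in the sgPSTK D7 libraries and between 180 and 212 CPM in the sgLuc D7 libraries, while in the D4 columns the groups overlapped.

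Several selenoprotein transcripts fell in the D7 columns of the sgPSTK cells. GPX1, a glutathione peroxidase, fell from 194 ± 13.7 to 70.9 ± 4.60 CPM (SD, n = 4), a log2 fold change of -1.45 (SE 0.0684, edgeR adjusted p = 2.8e-08). SELT (SELENOT) fell by 0.99 on the log2 scale (adjusted p = 0.0024), SEPW1 (SELENOW) by 0.73 (adjusted p = 1.5e-05) and C11orf31 (SELENOH) by 0.69 (adjusted p = 2.0e-05). SEPN1 (SELENON) fell by 0.50 (adjusted p = 0.0016). GPX4, the peroxidase that reduces lipid hydroperoxides in membranes, fell by 0.42 on the log2 scale, from 354 ± 29.9 to 264 ± 5.0 CPM (SD, n = 4; adjusted p = 0.00049). Among the other members the log2 fold changes were 0.15 for TXNRD1, 0.02 for TXNRD2 and 0.17 for MSRB1, none past the threshold. Of the 18 measured members 7 had a positive log2 fold change, and the median was -0.20.

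Of the 25 selenoproteins listed, 18 were measured, and in the D7 columns 6 fell, 0 rose and 12 did not pass. Adjusted over the list alone, 7 fell and 1 rose. The list was lower against the other genes by camera (adjusted p = 0.0081), a call that was lost with an estimated correlation (adjusted p = 0.188 with an estimated correlation). By fry the list had an adjusted p of 0.00035. GPX1 shares sequence with its pseudogene GPX1P1, which fell by 1.62 on the log2 scale, so the split of reads between them is uncertain.

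No selenoprotein passed the threshold in the D4 columns. GPX1 stood at 198 ± 33.7 CPM in sgLuc and 180 ± 27.5 CPM in sgPSTK (SD, n = 4), a log2 fold change of -0.14, and GPX4 had a log2 fold change of -0.02. SEPW1 had a log2 fold change of -0.51 (edgeR adjusted p = 1.0). In the summed counts GPX1 fell by 0.59 on the log2 scale (adjusted p = 0.015) and SEPW1 by 0.55 (adjusted p = 0.020), and the list had a camera adjusted p of 0.082 (2 lower adjusted over the list alone). The list passed without sgLuc 1 (adjusted p = 0.0123) and without sgPSTK 3 (adjusted p = 0.0412), and with limma voom (adjusted p = 0.00414). The selenoprotein list differed between the sets, with a lower D7 than D4 effect (camera adjusted p = 0.015), and this call was lost with an estimated correlation (adjusted p = 0.311 with an estimated correlation). For GPX1 alone the difference between the sets had an adjusted p of 0.0555. It passed without sgLuc 1 (adjusted p = 0.00039), without sgLuc 2 (adjusted p = 0.0181) and with no term for the sample (adjusted p = 0.00664), and missed the threshold without any other single sample (adjusted p of 0.102 to 0.365).

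**Figure D2:**
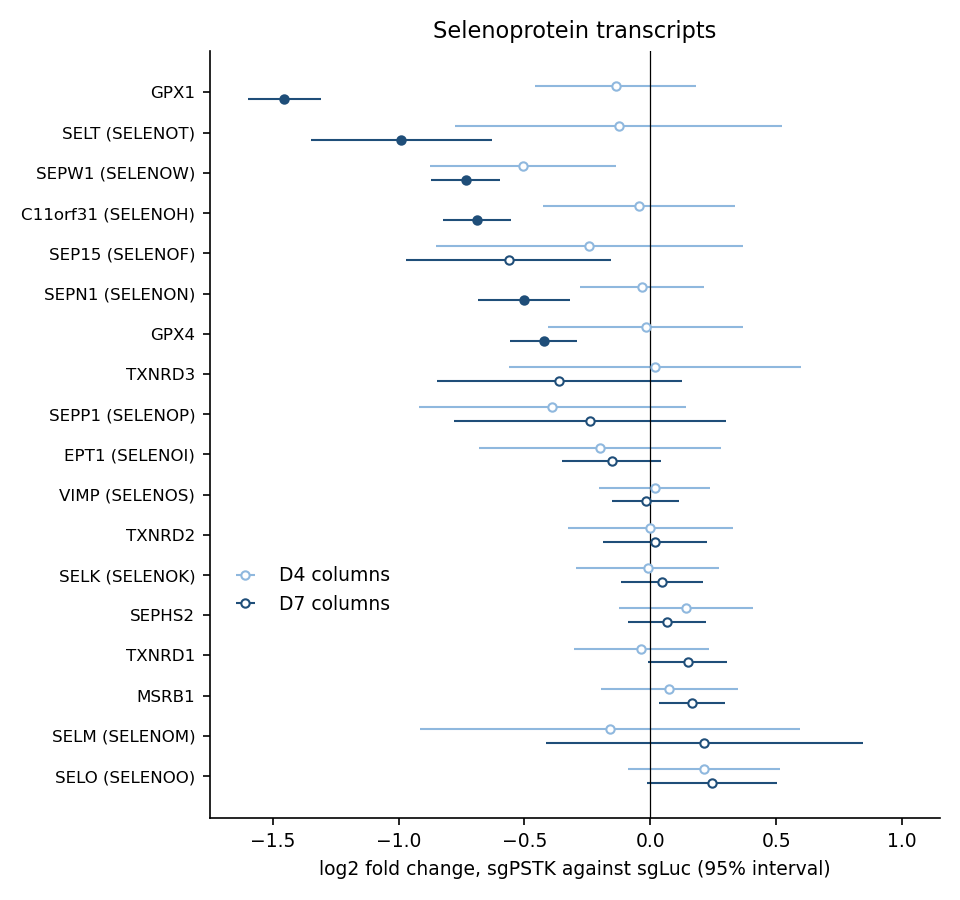
Log2 fold change of each measured selenoprotein transcript, sgPSTK against sgLuc, with its 95% interval, in the D4 columns (light) and the D7 columns (dark). Filled points passed the adjusted threshold, which 6 transcripts did in the D7 columns and 0 in the D4 columns.

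Genes that serve selenocysteine synthesis did not pass as a list in the D7 columns. Of the 13 measured members of that list, 0 rose and 2 fell in the D7 columns, SEPSECS (log2 fold change -0.55, edgeR adjusted p = 0.022) and TRIT1 (-0.25, adjusted p = 0.043). SEPSECS is the synthase that acts after PSTK, and TRIT1 modifies tRNA. The same 2 counts held adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.358). SEPSECS no longer passed without sgLuc 3 (adjusted p = 0.0576) or without sgPSTK 2, 3 or 4, and TRIT1 without sgLuc 1 (adjusted p = 0.115), sgLuc 3 or any 1 of the 4 sgPSTK samples.

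Across all genes, the sets gave very different numbers. In the D7 columns 1176 genes were higher and 910 lower in sgPSTK (edgeR, Benjamini-Hochberg, 15075 genes tested), and 347 of the higher and 23 of the lower ones changed more than 2-fold. In the D4 columns 0 were higher and 0 lower. An unadjusted edgeR p under 0.05 was reached by 473 of 15071 genes, fewer than the 5% that chance gives on average. In these columns DESeq2 called 2 higher and 1 lower and limma voom called 63 and 27. In the counts summed per sample, 304 genes were higher and 48 lower, against 613 and 264 by DESeq2. Genes whose sgLuc and sgPSTK values did not overlap made up 20.5% of those tested in the D7 columns, 3.07% in the D4 columns and 11.5% in the summed counts, where chance gives 2.86%.

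Single samples moved these counts. Without sgLuc 2, sgPSTK 1, sgPSTK 2 or sgPSTK 4 the summed counts gave 1 gene higher and 0 lower, CALY in each case, a gene singled out after its values were seen. They gave 490 and 121 without sgLuc 1, 108 and 7 without sgLuc 3, 768 and 793 without sgLuc 4 and 274 and 24 without sgPSTK 3. The D7 counts became 776 and 363 without sgLuc 1, 1401 and 1104 without sgLuc 2, 847 and 426 without sgLuc 3, and 1742 and 1690 without sgLuc 4. They became 873 and 441, 740 and 316, 1007 and 551, and 682 and 241 without sgPSTK 1, 2, 3 and 4 in that order.

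The fold changes of the sets were correlated across 15032 genes (Pearson r = 0.474, Spearman rho = 0.456), where genes are not independent replicates. Of 2082 genes called in the D7 columns, 1752 (84.1%) had the same sign in the D4 columns, with a median absolute log2 fold change of 0.149 there and 0.491 in the D7 columns. These genes were chosen by their D7 test, which favours the D7 value. For genes chosen in samples 1 and 2 and measured in samples 3 and 4 the medians were 0.067 in D4 and 0.361 in D7, and 0.222 and 0.738 with the samples exchanged. A direct test of the difference between the sets called 0 genes higher and 0 lower with edgeR, against 1302 at an unadjusted p under 0.05. It called 193 and 97 without sgLuc 1, 0 and 2 without sgLuc 2, and 6 and 2 with no term for the sample. The D4 library of sgLuc 1 stood apart, with a median correlation of 0.968 to the other libraries of its group and set, against 0.989 or more for the other 15 libraries. Without sgLuc 1 the D4 columns gave 1 gene higher, CALY, and 0 lower, while the genes at an unadjusted p under 0.05 went from 473 to 1334. Within sgLuc in the D7 columns, sgLuc 2 differed most. Its counts gave a chi-square per degree of freedom of 23.2 to 40.7 against the others, which differed among themselves by 5.56 to 8.75.

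**Figure D3:**
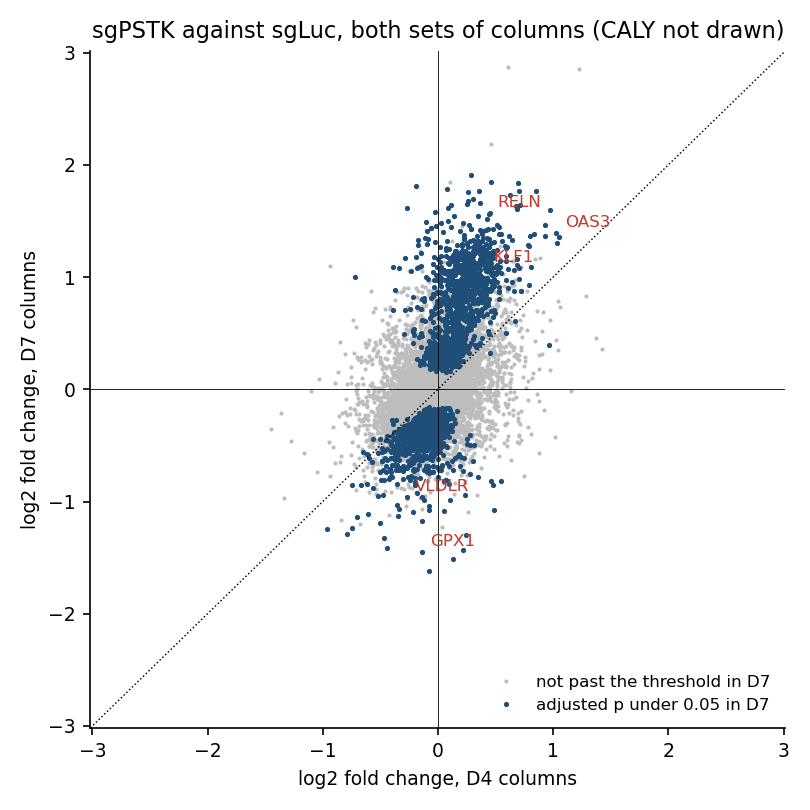
Log2 fold change of each gene, sgPSTK against sgLuc, in the D4 columns (horizontal) and the D7 columns (vertical), with genes past the adjusted threshold in the D7 columns in blue and the line of equal change dotted. CALY lies outside the drawn range and is not drawn, and the called genes had a median absolute change of 0.491 on the vertical axis and 0.149 on the horizontal one, where the choice by the D7 test favours the vertical axis.

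Some of the largest changes are given, for genes past the threshold with a mean of at least 2 CPM and no overlap between the groups. In the D7 columns RELN, a secreted matrix protein, rose from 5.89 ± 1.43 to 17.4 ± 3.26 CPM (SD, n = 4), a log2 fold change of 1.56 (SE 0.173, edgeR adjusted p = 9.4e-05). NEFH, a neurofilament chain, rose by 1.55 on the log2 scale, TGM2, a transglutaminase, by 1.44, ITGB5, an integrin chain, by 1.42 and OPTN, an autophagy receptor, by 1.41. PRR5, CAND2, MOB3B, EBI3, NRIP1 and BACH2 rose by 1.34 to 1.54. Among the falls, PLCH1 (a phospholipase C) fell by 1.12. VLDLR, a lipoprotein receptor, fell by 0.96 and SORL1, a sorting receptor, by 0.94. SPATA7 fell by 0.96. The pseudogenes PGK1P2, CALM2P2, PPP1R2P3 and RPL3P9 fell by 0.85 to 0.99 on the log2 scale, and their reads can be shared with their parent genes. CALM2P2 no longer passed without sgPSTK 2 (adjusted p = 0.0714) or sgPSTK 4, nor PPP1R2P3 without sgPSTK 4 (adjusted p = 0.0547). In the summed counts RELN, MMP9 (0.97), LTB (0.96), CAND2, PTPRF, IFI27, TGM2, LTBP1, PNMAL1, OPTN, SPTB and DAPK1 were among the largest log2 rises, and PLCH1, SORL1, VLDLR, LRRC8C, SOHLH2, MAP3K15, GPX1P1, ZNF654, GPX1, RTKN2 and HMGCS1 among the largest falls. None of these summed calls held in every fit with 1 sample left out.

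Erythroid transcripts were higher together in the sgPSTK than in the sgLuc cells in the D7 columns. From D4 to D7 the list was lower in both groups, by a median log2 change of -1.03 in sgLuc and -0.45 in sgPSTK. Of the 13 measured members of the erythroid and megakaryocyte list, 11 rose and 0 fell (12 and 0 adjusted over the list alone), with a median log2 fold change of 0.94. KLF1, an erythroid transcription factor, rose from 14.2 ± 1.75 to 30.1 ± 3.62 CPM (SD, n = 4; edgeR adjusted p = 5.2e-05). GATA1 rose from 23.5 ± 2.87 to 41.2 ± 3.72 CPM, the fetal globin gene HBG2 from 87.9 ± 13.2 to 167 ± 11.9 CPM and ALAS2, the erythroid enzyme that starts heme synthesis, from 9.69 ± 0.933 to 18.6 ± 1.24 CPM (SD, n = 4). HBG2 shares reads with the near-identical HBG1. Camera gave an adjusted p of 4.2e-11, and the call was lost with an estimated correlation (adjusted p = 0.163 with an estimated correlation). Among the D4 columns 0 members passed and the median was 0.29 (camera adjusted p = 7.9e-06; adjusted p = 0.389 with an estimated correlation), and the D4 call was lost without sgLuc 1 (adjusted p = 0.0723). The D4 library of sgLuc 1, which stood apart, had the lowest KLF1 level of its group, at 23.8 CPM. The D7 effect was larger than the D4 effect (camera adjusted p = 3.8e-06 on the difference; adjusted p = 0.311 with an estimated correlation). The list for iron and heme handling went the same way, with 8 of 25 higher and 0 lower in the D7 columns (9 and 2 adjusted over the list alone). BLVRB, a biliverdin reductase, rose from 32 ± 4.41 to 57.5 ± 3.77 CPM, and FECH, which inserts iron into heme, from 16.2 ± 1.03 to 24.4 ± 0.560 CPM (SD, n = 4). Camera gave an adjusted p of 0.0071 for that list (adjusted p = 0.163 with an estimated correlation).

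**Figure D4:**
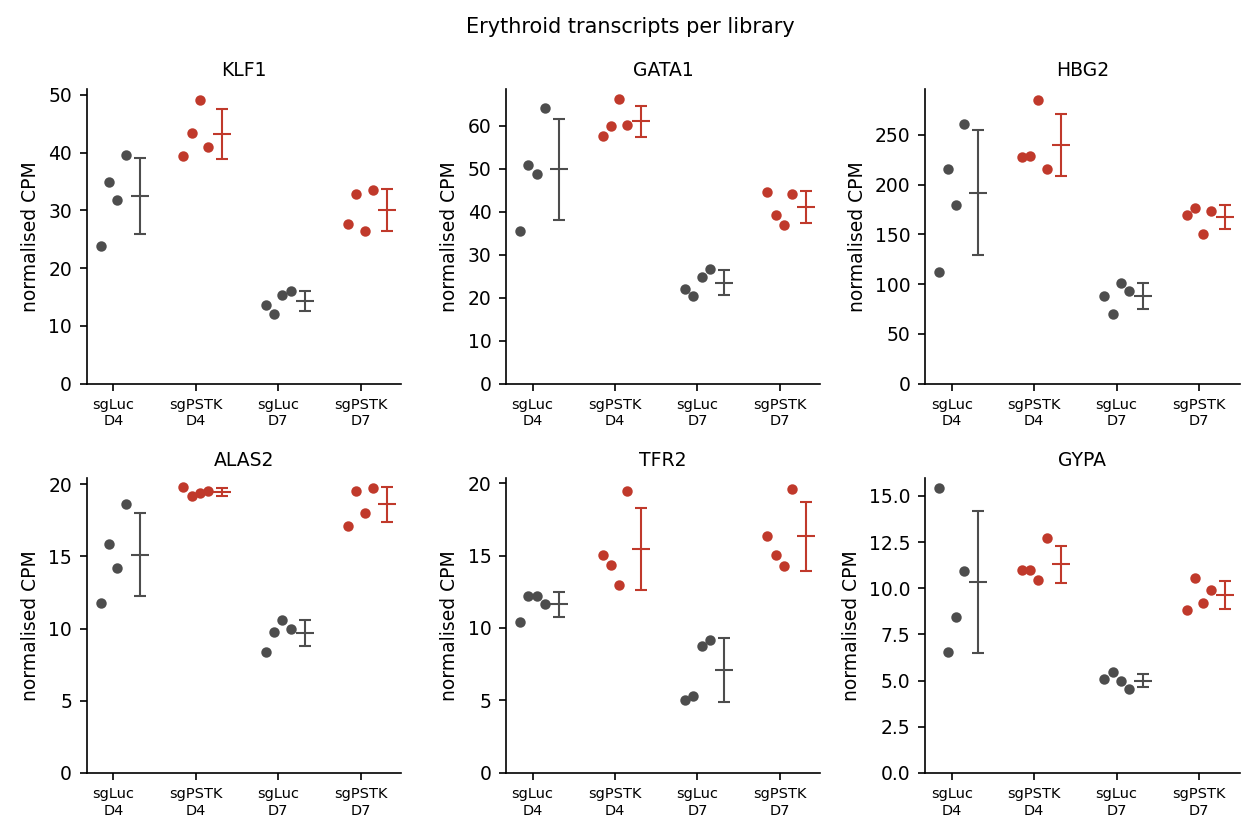
Normalised CPM of 6 erythroid transcripts in each library (points, 4 per group and set), with the mean and SD beside the points and every axis starting at 0. KLF1 lay between 26.3 and 33.5 CPM in the sgPSTK D7 libraries and between 12.1 and 16 CPM in the sgLuc D7 libraries.

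Transcripts of the NRF2 target list rose in part. In the D7 columns 7 of 21 measured targets rose and 1 (TXN, thioredoxin) fell (8 and 1 adjusted over the list alone), the TXN call being lost without sgLuc 1 (adjusted p = 0.104), sgLuc 3 or any 1 of the 4 sgPSTK samples. The ferritin chains FTL and FTH1 rose by log2 fold changes of 0.41 and 0.43, from 2766 to 3679 CPM and from 628 to 848 CPM. The heme transporter SLC48A1 rose by 0.41. Camera gave an adjusted p of 0.0021 (adjusted p = 0.163 with an estimated correlation). The estimated correlation of this list was -0.0144, below the preset 0.01, so a higher correlation does not explain that loss. FTL and FTH1 also belong to the iron and heme list and to the ferroptosis list, so these lists share rises. Of 21 ferroptosis members 6 rose and 1, GPX4, fell, or 6 and 5 adjusted over the list alone. Up to 4 fell with 1 sample left out, and the ferroptosis list was not called (camera adjusted p = 0.680). In the glutathione and thioredoxin list 2 of 29 rose and 5 fell (3 and 6 adjusted over the list alone), among them PRDX3 (-0.47), a mitochondrial peroxiredoxin, and GLRX (-0.40), with no call for the list (camera adjusted p = 0.680).

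Sugar and amino acid metabolism genes went both ways. In the glycolysis and hypoxia list 3 of 29 rose and 10 fell in the D7 columns, and 4 and 10 adjusted over the list alone (camera adjusted p = 0.024; adjusted p = 0.49 with an estimated correlation). HK1 rose from 42.2 ± 7.75 to 98.1 ± 9.65 CPM (SD, n = 4), while the other hexokinase, HK2, fell by 0.46 on the log2 scale and BNIP3, a mitophagy receptor, from 101 ± 9.80 to 57.7 ± 5.84 CPM. In the ATF4 list 3 of 27 rose and 8 fell, and 4 and 9 adjusted over the list alone (camera adjusted p = 0.042; adjusted p = 0.49 with an estimated correlation), including DDIT4 (log2 fold change -0.55), the serine synthesis enzymes PHGDH (-0.32) and PSAT1 (-0.35) and the asparagine synthetase ASNS (-0.34), while CHAC1 rose from 0.621 to 1.54 CPM. The glycolysis call was lost without sgLuc 3 (adjusted p = 0.0642) or sgPSTK 3 (adjusted p = 0.0527), and the ATF4 call without sgLuc 1 (adjusted p = 0.207), sgLuc 4, sgPSTK 2 or sgPSTK 4. In the list of nuclear oxidative phosphorylation genes 0 of 31 rose and 7 fell, and 0 and 12 adjusted over the list alone (camera adjusted p = 0.0071; adjusted p = 0.49 with an estimated correlation), with ATP5A1 (ATP5F1A) at -0.31. The cholesterol synthesis list did not pass in the D7 columns (2 of 25 higher and 5 lower, or 3 and 10 adjusted over the list alone; camera adjusted p = 0.0966), with FDFT1, squalene synthase, at -0.43.

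In the NF-kB list 5 of 26 rose and 0 fell, and 6 and 0 adjusted over the list alone (camera adjusted p = 0.0013; adjusted p = 0.49 with an estimated correlation). The chemokine CCL5 rose from 336 ± 35.4 to 580 ± 59.5 CPM (SD, n = 4), TNFAIP2 from 18.0 to 30.4 CPM and NFKB2 from 29.0 to 42.5 CPM. Of 19 replication-dependent histone genes 7 rose and 0 fell, and 9 and 0 adjusted over the list alone (camera adjusted p = 0.00053; adjusted p = 0.347 with an estimated correlation), led by HIST1H1C (141 to 256 CPM), HIST1H2BK (77.3 to 133 CPM) and HIST1H2BJ (a log2 fold change of 0.86). Most replication-dependent histone transcripts lack a poly(A) tail, and the libraries selected for one. In the monocyte and macrophage list 4 of 19 rose and 0 fell, and 7 and 0 adjusted over the list alone (camera adjusted p = 0.00057; adjusted p = 0.163 with an estimated correlation), with the lysosomal protease CTSD at a log2 fold change of 0.41 and the Fc receptor FCGR1A at 0.53. The lysosome and autophagy list gave 3 of 28 higher and 0 lower (7 and 1 adjusted over the list alone), with the autophagy adaptor SQSTM1 at 0.54 (camera adjusted p = 0.024; adjusted p = 0.163 with an estimated correlation). That call was lost without sgLuc 4 (adjusted p = 0.0568). CTSD belongs to both the monocyte and the lysosome lists, so their calls are not independent. In the G2/M list 0 of 30 rose and 4 fell, and 0 and 6 adjusted over the list alone (camera adjusted p = 0.0021; adjusted p = 0.49 with an estimated correlation), and the 4 became 0 without sgLuc 3, sgPSTK 1, sgPSTK 2 or sgPSTK 4. MYC fell from 457 ± 51.6 to 311 ± 20.3 CPM (SD, n = 4).

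**Figure D5:**
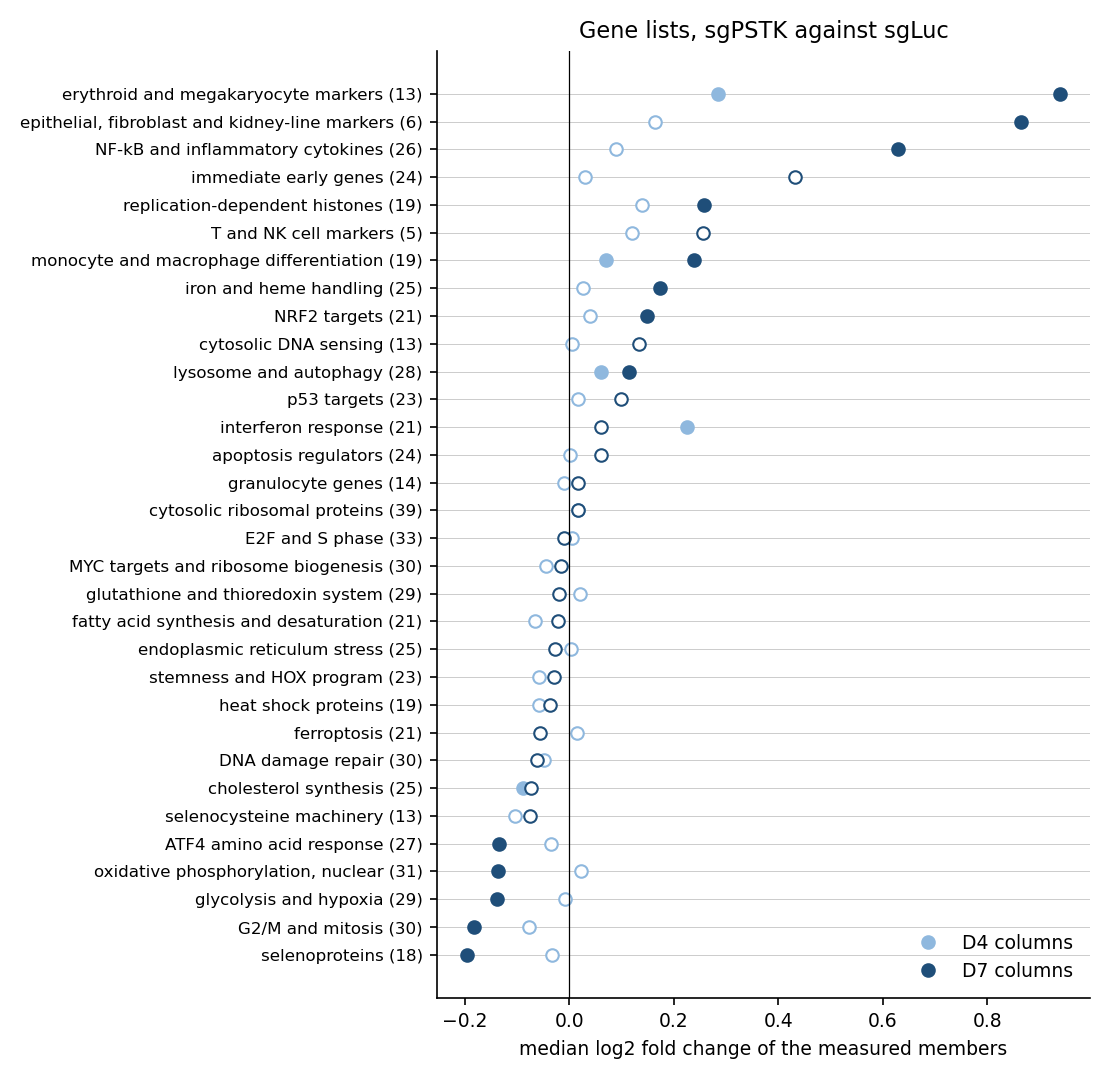
Median log2 fold change of the measured members of each gene list, sgPSTK against sgLuc, in the D4 columns (light) and the D7 columns (dark), with the number of measured members in brackets. Filled points passed camera's adjusted threshold with the preset correlation, and the erythroid list lay furthest to the right in the D7 columns at 0.94.

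Of the 21 measured interferon-response genes, 17 in the D4 columns had a positive fold change and 0 passed over all genes, while 4 rose adjusted over the list alone (camera adjusted p = 1.3e-08; adjusted p = 0.0947 with an estimated correlation). OASL, at 0.613 ± 0.128 CPM in sgLuc and 1.5 ± 0.330 CPM in sgPSTK, had a log2 fold change of 1.28, OAS3 1.03, IFI27 0.86 and IFI6 0.45 in the D4 columns. In the summed counts these 4 genes rose (edgeR adjusted p of 0.024 for OASL, 0.028 for OAS3, 0.019 for IFI27 and 0.021 for IFI6; camera adjusted p = 0.00039; adjusted p = 0.154 with an estimated correlation), and 8 rose adjusted over the list alone. The cholesterol synthesis (adjusted p = 0.033), lysosome (adjusted p = 0.033) and monocyte (adjusted p = 0.0404) lists also passed camera in the D4 columns, each with an adjusted p of 0.389 with an estimated correlation. The cholesterol and monocyte calls were lost without sgLuc 2 (adjusted p = 0.0766) and the lysosome and monocyte calls without sgLuc 1 (adjusted p of 0.147 and 0.506), among other single samples. In the D7 columns 4 of 21 rose and 1 fell (5 and 2 adjusted over the list alone), and only 1 rose without sgLuc 1, sgLuc 3, sgPSTK 2 or sgPSTK 4, with OAS3 at a log2 fold change of 1.39 and the list not past the threshold (camera adjusted p = 0.0966). The difference between the sets had a camera adjusted p of 0.124 for the list.

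Of the lists for other cell types, the epithelial, fibroblast and kidney-line list rose in the D7 columns, with 4 of 6 measured members higher and 0 lower, and 4 and 1 adjusted over the list alone (camera adjusted p = 0.0015; adjusted p = 0.188 with an estimated correlation). KRT19 rose from 16.2 ± 1.83 to 30.9 ± 2.10 CPM, KRT18 from 21.8 ± 3.42 to 43.0 ± 5.4 CPM and KRT8 from 37.1 ± 4.51 to 64.4 ± 7.11 CPM (SD, n = 4). The T and NK cell list had 2 of 5 members higher and 1 lower, the same adjusted over the list alone, and did not pass (camera adjusted p = 0.509). B cell markers (4 of 16 measured) and MHC class II genes (1 of 12 measured) were too few to test, and of the 13 mitochondrial genome genes 0 were listed. Genes with few reads are not listed, so unlisted members may be little expressed, which was not tested. Of 14 granulocyte genes 2 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.680), with MMP9 rising from 9.32 ± 1.61 to 20.1 ± 1.69 CPM and MPO falling from 6647 ± 228 to 5447 ± 275 CPM (SD, n = 4).

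In the counts summed per sample 11 lists passed by camera, and none of them with an estimated correlation (adjusted p of 0.154 to 0.568 with an estimated correlation). Over all genes and then adjusted over the list alone, 5 and 11 of 13 erythroid members rose (camera adjusted p = 3.6e-09), with KLF1 at a log2 fold change of 0.68 and ALAS2 at 0.64. For histones 3 and 9 of 19 rose (adjusted p = 0.0004), for the NF-kB list 1 and 4 of 26 (adjusted p = 0.005), and for the epithelial list 3 and 4 of 6 (adjusted p = 0.014). For NRF2 targets 1 and 2 of 21 rose (adjusted p = 0.0255), and for iron and heme handling 1 and 7 of 25 (adjusted p = 0.0299). For the lysosome list 1 and 1 of 28 rose (adjusted p = 0.0051), and for the monocyte list 0 and 4 of 19 (adjusted p = 0.0004). Of 30 G2/M genes 0 passed either way (adjusted p = 0.0051). In cholesterol synthesis 3 of 25 fell and 1 rose, and 10 and 2 adjusted over the list alone (adjusted p = 0.0279), with HMGCS1 at -0.58, MSMO1 at -0.37 and FDFT1 at -0.25. The cholesterol, NRF2 and iron calls were lost without sgLuc 3 (adjusted p of 0.0976, 0.0508 and 0.0731) or sgLuc 4, the NF-kB call without sgLuc 4 or sgPSTK 1 (adjusted p = 0.203), and the epithelial call without sgLuc 4 (adjusted p = 0.0563). The cholesterol call was also lost without sgPSTK 3 or sgPSTK 4. Without sgLuc 2, sgPSTK 1, sgPSTK 2 or sgPSTK 4 no member of any list passed over all genes in the summed counts.

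The other lists did not pass by camera in the D7 columns. For endoplasmic reticulum stress 5 rose and 2 fell (5 and 3 adjusted over the list alone; adjusted p = 0.553), with SDF2L1 at a log2 fold change of 0.50. For p53 targets 2 rose and 0 fell (the same over the list alone; adjusted p = 0.263), and 0 rose without sgPSTK 4. For DNA damage repair 1 rose and 2 fell (1 and 5 over the list alone; adjusted p = 0.0966), with APEX1 at -0.36, and for cytosolic DNA sensing 1 rose and 1 fell (the same over the list alone; adjusted p = 0.242). In the E2F and S phase list 3 rose and 5 fell (3 and 6 over the list alone; adjusted p = 0.680), and in the MYC list 1 rose and 3 fell (1 and 4 over the list alone; adjusted p = 0.843). Of the cytosolic ribosomal proteins 0 rose and 6 fell (the same over the list alone; adjusted p = 0.620), with RPL6 at -0.29. Fatty acid genes gave 3 higher and 3 lower (4 and 5 over the list alone; adjusted p = 0.772), with FADS1 at 0.40. The stemness and HOX list gave 4 higher and 2 lower (5 and 2 over the list alone; adjusted p = 0.467), with LAPTM4B at 0.96, and the apoptosis list 3 higher and 1 lower (the same over the list alone; adjusted p = 0.433), with BCL2L1 at 0.49 and BCL2 at -0.42. Heat shock proteins gave 3 higher and 2 lower (4 and 2 over the list alone; adjusted p = 0.772), with HSPA1A at 0.86, and immediate early genes 2 higher and 2 lower (the same over the list alone; adjusted p = 0.371). The median had the opposite sign to the test for ferroptosis, endoplasmic reticulum stress, stemness, heat shock and cytosolic ribosomal proteins.

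Single samples also moved the numbers of list members that passed over all genes in the D7 columns. With 1 sample left out, the erythroid list ranged from 9 to 12 higher and 0 lower, iron and heme from 7 to 9 higher and 0 to 2 lower, and NRF2 from 5 to 10 and 0 to 1. In the same order, ferroptosis ranged from 4 to 6 and 1 to 4, histones from 5 to 8 and 0, NF-kB from 3 to 5 and 0 to 1, and monocyte genes from 2 to 6 and 0. The lysosome list ranged from 2 to 7 and 0 to 3, the epithelial list from 4 to 5 and 0, interferon from 1 to 5 and 0 to 1, and p53 targets from 0 to 5 and 0 to 1. Endoplasmic reticulum stress ranged from 3 to 6 and 0 to 2, selenoproteins from 0 to 1 and 6 to 7, and selenocysteine synthesis from 0 to 1 and 0 to 2. Glycolysis ranged from 1 to 4 and 5 to 12, ATF4 from 1 to 5 and 6 to 12, oxidative phosphorylation from 0 to 1 and 1 to 11, and G2/M gave 0 and 0 to 11. Cholesterol ranged from 0 to 3 and 2 to 9, cytosolic ribosomal proteins from 0 to 4 and 1 to 7, E2F from 2 to 5 and 1 to 6, and glutathione from 1 to 4 and 2 to 6. The MYC list ranged from 0 to 3 and 1 to 5, DNA repair from 0 to 2 and 1 to 5, cytosolic DNA sensing from 1 to 2 and 0 to 1, and stemness from 3 to 6 and 1 to 2. Fatty acids ranged from 2 to 4 and 1 to 6, apoptosis from 1 to 4 and 1 to 2, and heat shock from 1 to 3 and 0 to 3. Immediate early genes ranged from 0 to 3 and 1 to 3, granulocyte genes from 1 to 4 and 1 to 2, and T and NK cell markers from 1 to 2 and 1.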

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

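The tests on the sgLuc 1 D4 library, on the noise of the D4 columns, on the D4 splits, on the erythroid share and scaling and on CALY were chosen after the results were seen.

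The first pattern is the gap between 0 called genes in the D4 columns and 2086 in the D7 columns. In D4, 473 of 15071 genes had an unadjusted edgeR p under 0.05, fewer than the 5% that chance gives on average. There DESeq2 called 2 higher and 1 lower, and limma voom 63 and 27. In the D7 columns the real split was the 1 of 35 splits of the samples with as many genes, the highest other split giving 0. The same held for the 352 summed calls (1 of 35, highest other 0). Every other split mixes the groups, which widens its spread where they differ, and 35 splits are few, so chance is not excluded. Among the D4 columns all 35 splits gave as many as the real 0, the highest other giving 0, which follows from a count of 0 and says nothing about chance. The spread of the sgLuc 1 D4 library is argued against only as the whole cause, since the D4 columns without it gave 1 gene against 776 higher and 363 lower in D7. Without it the D4 genes at an unadjusted p under 0.05 went from 473 to 1334, so a part of the gap stays open to it. Equal effects behind more noise are argued against by the ratio of D4 to D7 change of 0.186 for genes chosen in the other samples (0.301 with the samples exchanged). A smaller effect in the D4 columns may remain as a hypothesis, while the direct test of the difference called 0 genes, or 193 higher and 97 lower without sgLuc 1.

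The second pattern is the higher level of the erythroid list in sgPSTK than in sgLuc in the D7 columns. From D4 to D7 the list was lower in both groups (median log2 change -1.03 in sgLuc and -0.45 in sgPSTK). Depth is argued against by a list median of 0.948 with every library thinned to 21864400 reads, and scaling, which moves every gene alike, by a list median 0.955 above that of all other genes with library totals alone (lower quartile of the members 0.827 above). A larger share of erythroid-type cells or of their RNA may also raise these transcripts and cannot be told apart from a change within cells. Its members rose by unequal amounts (common log2 fold change 0.86, chi-square heterogeneity p of 2.48e-09 across 13 genes), from EPOR at 0.04 to HBA1 at 1.22, and bulk RNA does not show which cells carry them.

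The third pattern is CALY, chosen after its values were seen. The sgPSTK columns held 13 to 52 CALY reads each and the sgLuc columns 0 to 2, with 6 of the 8 sgLuc columns at 0. Over the D4 columns the level was at least 42.1-fold higher by the lower 95% counting limit (148 reads against 0; 52.4-fold against a floor of 3 counts over the group), and over the D7 columns the ratio was 23.1 (60 reads against 3, 95% counting interval 7.52 to 115). Reads entering a single library are argued against by the lowest sgPSTK count of 13. The summed median log2 fold change differed by 0.021 between the 41 genes beyond PSTK and the 331 on its near side. That small difference argues only against a copy number change shared by the whole chromosome arm beyond PSTK. Of the 41 genes, 5 passed as higher and 3 as lower, and a median cannot show a change of part of the arm. Such a change or an effect local to CALY may remain as hypotheses, and neither was tested.

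The effect of sgPSTK differed between the D7 and the D4 columns for 8 lists by camera on the difference. The adjusted p was 0.0151 for selenoproteins, 0.00013 for oxidative phosphorylation (both lower in D7), 0.00616 for NRF2 targets, 4.0e-06 for NF-kB and inflammatory cytokines, 0.037 for monocyte genes, 0.00388 for histones, 3.8e-06 for erythroid genes and 0.00159 for epithelial and related genes. None passed with an estimated correlation (adjusted p of 0.311 to 0.643 with an estimated correlation).

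In 14 of 348 groups of 4 samples 1 sample lay far from the others, where chance gives about 5%. In normalised CPM of the D7 columns, TXNRD1 in sgPSTK 1 was 160 (others 175 to 177), TNFAIP2 in sgLuc 2 was 15.3 (18.7 to 19), MYC in sgLuc 4 was 380 (481 to 485) and BNIP3 in sgLuc 4 was 86.1 (105 to 107). APEX1 in sgLuc 4 was 273 (300.3 to 304) and TP53I3 in sgLuc 1 was 0.199 (0.313 to 0.331). In the D4 columns OAS3 in sgPSTK 1 was 4.70 (3.13 to 3.18), OASL in sgLuc 3 was 0.423 (0.647 to 0.692) and SELT in sgLuc 1 was 56.2 (20.7 to 25.8). In the summed counts PSTK in sgPSTK 4 was 5.58 (4.54 to 4.70), OPTN in sgLuc 2 was 2.30 (3.01 to 3.14), GPX1P1 in sgPSTK 4 was 9.42 (13.1 to 13.6), ZNF654 in sgPSTK 3 was 3.09 (3.94 to 4.02) and MSMO1 in sgPSTK 1 was 53.8 (57.0 to 57.4).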

How the results depend on the processing

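The fits over the D4 and the D7 columns, the voom fits over 16 and 14 columns and the fit with no sample term were chosen after seeing the data. For values that moved, the cause was not tested, except that leaving out a sample leaves fewer samples and a test against 1.5-fold asks for a larger change. With DESeq2 size factors, library totals alone or no filter the summed and D7 counts stayed within 1.5 times (summed 272 to 304 higher and 40 to 48 lower, D7 1204 to 1244 and 834 to 864), and scaling moved the median gene by under 0.02 on the log2 scale. In the summed counts the DESeq2 Wald test gave 613 higher and 264 lower and PSTK at -0.35, limma voom 1003 and 695, PSTK at -0.39 and the selenoprotein list at an adjusted p of 0.00414, the replicate block 399 and 113, and the test against 1.5-fold 1 and 0. Voom over 16 columns gave 496 and 102 and PSTK at -0.35 (adjusted p = 0.0337), voom over 14 columns 473 and 215, PSTK at -0.30 (adjusted p = 0.0826) and the selenoprotein list at 0.0117, and fry put that list at 0.014. The higher share of calls was 86.4% with edgeR, 69.9% with DESeq2 and 59.1% with voom. In the D4 columns DESeq2 size factors gave 1 gene higher, the DESeq2 Wald test 2 higher and 1 lower and voom 63 and 27. In the D7 columns voom gave 1910 and 1850, the test against 1.5-fold 94 and 4, and the selenoprotein list an adjusted p of 0.188 with an estimated correlation. Of the lists called by camera, fry kept 11 of 13 in the D7 columns and 8 of 11 in the summed counts, and lost all 5 in the D4 columns. It added 1 list in the D7 columns and 4 in the summed counts. The difference between the sets gave 6 higher and 2 lower with no sample term.

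With 1 sample left out, the summed counts ranged from 1 to 768 higher and from 0 to 793 lower, D4 from 0 to 1 and 0 to 0, D7 from 682 to 1742 and from 241 to 1690, and the difference between the sets from 0 to 193 and from 0 to 97. PSTK ranged from -0.42 to -0.32 in the summed counts, -0.42 to -0.29 in D4 and -0.43 to -0.28 in D7. The selenoprotein list ranged from an adjusted p of 0.0123 to 0.142 summed, 0.587 to 0.995 in D4 and 0.00663 to 0.0194 in D7. The direction of the cytosolic ribosomal protein list reversed in the summed counts without sgLuc 1 (adjusted p = 0.0412) and with voom over 14 columns (adjusted p = 3.6e-05), and in D4 without sgLuc 1 (adjusted p = 0.0128) and with voom (adjusted p = 2.8e-08). Its adjusted p with 1 sample left out ranged from 0.0412 to 0.815 summed and from 0.00488 to 0.6998 in D4. At the D4 depth and spread per gene, with no library set apart, the fit recovered 1.79% of simulated changes of 1.3-fold, against 39.5% in D7.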

Other observations

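Within each group the D7 columns also differed from the D4 columns. In the sgLuc samples 150 genes were higher and 527 lower in D7 (0 to 1217 and 4 to 1398 with 1 sample left out), and in the sgPSTK samples 2101 and 2023 (1169 to 2522 and 1084 to 2306). The erythroid list had a median log2 change from D4 to D7 of -1.03 in sgLuc and -0.45 in sgPSTK (camera adjusted p of 1.3e-07 and 0.00399; adjusted p of 0.411 and 0.570 with an estimated correlation). The epithelial list changed by -1.29 and -0.60 (camera adjusted p of 0.0012 and 0.0043) and the histone list by -0.63 and -0.47 (6.1e-08 and 0.0010). For the monocyte list the changes were -0.46 and -0.33 (3.5e-07 and 0.0010) and for the lysosome list -0.15 and -0.21 (0.0051 and 0.0076). None of these passed with an estimated correlation (adjusted p of 0.411 to 0.584). The interferon list was lower in D7 in both groups (camera adjusted p of 0.0326 in sgLuc and 0.0010 in sgPSTK). The selenoprotein list was lower in sgPSTK (median -0.33, camera adjusted p = 0.0043) and did not pass in sgLuc (median -0.02, adjusted p = 0.553). Oxidative phosphorylation (0.00023) and glycolysis (0.0043) were also lower in sgPSTK and did not pass in sgLuc. With an estimated correlation these were lost too (adjusted p of 0.411 to 0.570). The NRF2, iron and NF-kB lists did not pass in either group. The first principal component held 33.3% of the variance and the next 22.1%. On the first, the sgLuc D7 libraries lay at 23.3 to 45.4 and the sgPSTK D7 libraries at 2.35 to 9.23. The D4 libraries lay at -34.5 to -16.8, except sgLuc 1 D4 at 15.7. That library also lay furthest out on the next component, at 56.8.

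HBE1 and PRAME were chosen after their values were seen. Over the 16 columns the mean level was 5850 CPM for MPO and 4526 CPM for PRTN3, both granule proteins, 894 CPM for the embryonic globin gene HBE1, 44.0 CPM for GATA1 and 192 CPM for PRAME. It was 10.7 CPM for LYZ, 5.84 CPM for ITGAM, 1.61 CPM for HOXA5, 1.3 CPM for MEIS1 and 0.850 CPM for CEBPA. Of the other monocyte genes SPI1 stood at 466 CPM, CTSD at 233 CPM and S100A9 at 44.0 CPM. Of the other stemness and HOX genes MYB stood at 196 CPM, RUNX1 at 77.7 CPM and HOXA10 at 77.5 CPM. Only 19 of 33 monocyte genes and 23 of 37 stemness and HOX genes were measured. The identity of the cells was not tested.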
